A study of Mus musculus with 2 samples.

How the data were processed

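Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts open chromatin and tags it for sequencing, in midbrain tissue of newborn mice (day 0) of strain B6NTac;B6NCrl/Lap. Per the labels, there were 2 biological replicates of 1 group, each a pool of male and female pups, with a single technical replicate each and a fragment size range of 200 to 750 bp. The pool of replicate 1 held 15 pups, and the labels used here give no number for replicate 2. The design holds no second tissue, age or treatment, so it allows a description of open chromatin and a comparison of the replicates, with no test between conditions. With n = 2, an SD measures only the difference between these pools.

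The deposited files were peak lists on genome build mm10, per the file headers and the accompanying text files. For each library the authors deposited a list of peaks found in pseudoreplicates, an IDR-thresholded list and an IDR-ranked list, where IDR is the irreproducible discovery rate, a measure of how well peak ranks repeat. For the whole series there were a replicated list, a pseudoreplicated list, a conservative and an IDR-thresholded list, and 2 IDR-ranked lists, all made by the authors from both libraries. The aligner, the peak caller, their versions and any shift of reads to the transposase cut site were not given in the sources used here. Read depth was not analysed here, so the precision of a single peak is unknown, and intervals on shares of peaks cover counting error only.

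The signal value of each peak is the authors' enrichment value and was used only to describe, rank or filter peaks within a list. The deposited −log10 q value of each peak was used for a stricter threshold of 5. The score that the authors deposited in the ranked lists, a global IDR on a logarithmic scale, was not used in any calculation. In the series' ranked lists, 4 value columns that belong to the input peak sets were not mapped to a sample and were not used. The ranked list that contained every peak of the conservative list was taken as the one made from the true replicates.

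Peaks were counted as entries, each with its own summit, and several entries can share a region. Each summit was placed in the first class that applied, of promoter (within 1000 bp of a transcription start site of a protein-coding gene), other start site, exon, intron and intergenic, with the comprehensive GENCODE M21 annotation on GRCm38, the assembly behind mm10. A protein-coding gene was called open in a library when a summit lay within 1000 bp of any of its start sites, and closed when none was listed there, which at unknown depth does not show that the promoter is inaccessible. A peak outside these windows was called distal and was given to the gene with the nearest start site within 100000 bp; such an assignment does not show that the peak regulates the gene.

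Before the data were examined, 27 gene lists (418 members, 417 of them in the annotation) and 30 consensus motifs were fixed. Each list was set beside 10000 random lists of the same size, matched on the promoter CpG ratio (observed over expected, start site ± 500 bp, 10 bins) for promoters and on the length of sequence nearest to the gene (10 bins) for distal peaks. The percentile of a list describes these libraries and is not a p-value. A list was called below or above random when it lay outside the central 95% of random lists, below the percentile 2.5 or above 97.5, in both libraries. For motifs, the share of windows (summit ± 100 bp) with the consensus on either strand was divided by the share in windows without peaks centred 1000 bp to each side. Overlap between replicates required 1 bp, and chance overlap came from 100 seeded shuffles of regions within chromosomes, outside assembly gaps. Exact Clopper-Pearson intervals at 95% were given for shares of single libraries.

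The genes named in the text followed a rule fixed in advance. Per list, these were up to 4 members open in both libraries with the highest signal value in the replicated list, and up to 4 members open in neither, in alphabetical order. For distal peaks they were up to 3 members per list with the most peaks and the 10 genes with the most among all genes. A fixed set of midbrain and regional factors was always named, as were the 10 strongest entries outside promoters and the 5 strongest in promoters. The motifs named were the 6 with the highest and the 3 with the lowest ratio at distal peaks, and those with a ratio above 1.5 at one kind of peak and below 1.1 at the other. Anything else named was chosen after its values were seen, and the text says so.

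Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, bedtools 2.31.1 for shuffling, blastn 2.17.0 for sequence matches and matplotlib 3.10.9 for plots. The steps were tested on simulated data. Of 20 simulated lists with lowered promoter openness over 21911 genes, 19 were placed outside the central 95% in both libraries, and 0 of 20 unchanged lists were. For simulated distal counts over 21911 genes these numbers were 19 of 20 and 0 of 20. The simulated libraries were drawn independently of each other, whereas the real libraries share most of their open promoters. The 0 of 20 therefore does not give the rate of false calls for the real lists. Each planted change had a single fixed size, so 19 of 20 need not hold for weaker changes. Of 5000 simulated regions, 3500 were made to overlap and 3500 were found, and 1000 of 1000 planted CTCF motifs were recovered among 5000 windows. Alternatives covered the peak list, the threshold, promoter windows of 500 and 2500 bp, distal limits of 50000 and 200000 bp, the matching of random lists, a reciprocal overlap of 50%, the motif background and window, and leaving out each replicate; those added after the data were seen were the basic transcript set, counting each region once, and leaving out soft-masked summits. Peaks on unplaced contigs were left out of all comparisons.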

Results

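Open chromatin of the newborn mouse midbrain was mapped by ATAC-seq in 2 pools of pups, called replicate 1 and replicate 2. The midbrain holds dopaminergic, GABAergic, glutamatergic and serotonergic neurons along with glia, vessels and late progenitors, so each peak list is a mixture of cell types. Replicate 1 had 81993 peak entries in 39730 regions and replicate 2 had 66120 entries in 38078 regions. These regions covered 27.5 Mb and 22.0 Mb, or 1.04% and 0.829% of the assembled genome. Median region width was 569 bp in replicate 1 and 461 bp in replicate 2. Because summits are listed separately, 51.5% of the entries of replicate 1 and 42.4% of those of replicate 2 were further summits of a region already listed.

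The first comparison asked how far the replicates shared their peaks, and promoters were shared far more than introns. Of the promoter summits of replicate 1, 92.6% lay in an entry that overlapped a peak of replicate 2, against 56.6% of its intronic summits. In the other direction these shares were 97.3% and 63.0%. Promoter entries made up 87.0% and 89.9% of the strongest decile by signal value in replicates 1 and 2, so location was not separated from peak strength here. Intergenic summits overlapped in 62.5% of cases from replicate 1 and 59.8% from replicate 2. Over all locations, 77.4% of the entries of replicate 1 (95% interval 77.1 to 77.6%) and 81.2% of those of replicate 2 (80.9 to 81.5%) overlapped the other replicate. Entries of a region share its ends and overlap together, so these intervals are too narrow even as counting error. By region the shares were 66.6% (95% interval 66.1 to 67.1%) and 72.0% (71.6 to 72.5%). Shuffled regions overlapped in 1.87% and 1.96% on average and in at most 2.05% and 2.15% of cases. The shared sequence came to 17.4 Mb, which is 63.3% of the sequence covered in replicate 1 and 79.2% of that in replicate 2.

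The strongest peaks were shared almost completely. In the strongest decile by the authors' signal value, 99.9% of the entries of replicate 1 and 100% of those of replicate 2 were found in the other library. In the third decile from the bottom the shares were 62.7% and 61.6%. The weakest decile stood above it, at 74.6% and 76.6%, and also held more promoter entries, 53.8% and 53.3%. An entry takes the overlap of its whole region, so a weak further summit of a shared region counts as shared. The rise therefore does not show that the weakest peaks repeat better. The IDR-thresholded lists held 44232 and 33749 entries, a self-consistency ratio of 1.31. The series' thresholded list had 55210 entries and its conservative list 50527, a rescue ratio of 1.09.

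**Figure D1:**
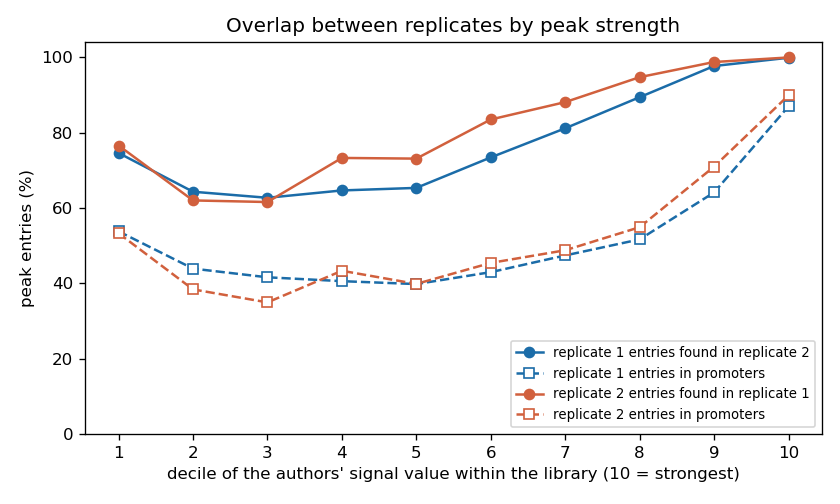
The share of peak entries of each replicate that overlap a peak of the other replicate (filled circles, %) and that have their summit in a promoter (open squares, %), by decile of the authors' signal value within the library. Both overlap lines are lowest in decile 3, at 62.7% and 61.6%, and reach 99.9% and 100% in decile 10.

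The next comparison placed the summits on the genome. Promoters of protein-coding genes held 51.7% ± 0.490 of the summits (SD, n = 2), although promoter windows make up 3.70% of the assembled genome, an enrichment of 14-fold. Every summit counted, and a region held 2.06 entries on average in replicate 1 and 1.74 in replicate 2. The shares here are therefore of summits and need not hold for regions, for which they were not calculated. Start sites of other genes held 4.29% ± 0.0622 (SD, n = 2) and exons 2.96% ± 0.175 (SD, n = 2). Introns held 20.3% ± 1.12 (SD, n = 2) and intergenic sequence 20.8% ± 0.866 (SD, n = 2), below their genome shares of 38.3% and 52.4%. The promoter share depended on the list, and rose to 76.9% in the IDR-thresholded lists.

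Of 21911 protein-coding genes, 13759 had an open promoter in replicate 1 and 13372 in replicate 2. Both libraries shared 13094 of them, and 7874 genes were open in neither. CpG-rich promoters, typical of housekeeping and developmental genes, were nearly all open: 98.6% and 97.49% of the genes in the highest of 10 bins of the CpG ratio had a peak. In the lowest bin the shares were 1.05% and 1.51%. The strongest promoter peaks in the replicated list lay at Hsd17b7, an enzyme of cholesterol synthesis (chromosome 1, 169968845 to 169969781, signal value 23.5), Tars, the threonyl-tRNA synthetase (chromosome 15, 11399269 to 11400105, 23.4), Tmem218 (chromosome 9, 37207647 to 37208631, 23.2), Ccdc89 (chromosome 7, 90426087 to 90426971, 23.2) and Fopnl (chromosome 16, 14316751 to 14317946, 23.0).

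Among the fixed gene lists, pan-neuronal, synaptic and ribosomal protein promoters were open throughout. Below, the number after a gene is the authors' signal value of its promoter peak in the replicated list, and counts of open genes are of genes open in both libraries. A gene called closed was open in neither library, and a number after it gives the peak it still had in the replicated list. All 16 pan-neuronal genes were open in both libraries, led by Nrxn1, a presynaptic adhesion protein (signal value 17.4), Syt1, the calcium sensor of synaptic vesicle release (13.8), Syn1, a synaptic vesicle protein (11.01), and Map2, a dendritic microtubule protein (10.5). All 16 genes of the synapse and activity-response list were open as well, with Egr1, an activity-induced transcription factor, at 9.82 and the glutamate receptor subunit Gria2 at 9.70, followed by Dlg4, which encodes the postsynaptic scaffold PSD-95, at 9.02 and the GABA receptor subunit Gabrb3 at 8.15. CpG-matched random lists averaged 80.7% and 82.1% open for these lists, which were the only ones of the 27 above random in both libraries. In the IDR-thresholded lists the synapse list was 84.4% open, within the random range. All 24 cytosolic ribosomal protein genes were open, at percentiles of 73.6 and 80.3, with Rps6 at 12.9, Rpl27 at 12.5 and Rps5 at 12.4. The peak of Rpl15 (15.1) also lay near the start site of another protein-coding gene.

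The radial glia and progenitor (96.9% open on average), cell cycle (96.9%), astrocyte (81.2%) and oligodendrocyte lineage (50%) lists were within the range of CpG-matched random lists, whose means were 89.1%, 94.3%, 71.2% and 55.96%. In the radial glia and progenitor list, 15 of 16 genes were open in both libraries, including Sox9 (7.98) and Sox2 (7.16), transcription factors of neural progenitors, the intermediate filament gene Vim (7.11) and Fabp7 (6.83), a radial glial fatty acid carrier. The cell cycle list also had 15 of 16 open, with the replication genes Mcm3 (18.3) and Pcna (17.6), the cyclin Ccna2 (17.2) and the spindle motor Kif11 (16.3). Of the astrocyte genes 12 of 16 were open, among them Nfia (8.32) and the glutamate transporter Slc1a2 (7.42), while the water channel Aqp4 and S100b were open in neither library. Glul, the glutamine synthetase gene (10.7), shared its peak with the start site of another gene. Of the oligodendrocyte lineage genes 7 of 16 were open, with the lineage factors Olig1 (5.81) and Olig2 (5.30), the progenitor receptor Pdgfra (5.02) and Ugt8a (8.05), an enzyme of myelin lipid synthesis. Another 7 were open in neither, including the myelin genes Cnp (2.62), Mag and Mog and the progenitor proteoglycan Cspg4.

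Midbrain neuron genes were mixed. Of 18 dopaminergic genes 10 were open in both libraries, led by En1 (6.33), Nr4a2 (6.10) and En2 (5.91), transcription factors of these neurons, and Slc6a3 (4.34), the dopamine transporter. Pitx3 (2.75), Lmx1a (2.85) and Otx2 (2.56), further factors of dopaminergic development, were also open in both. Th, the rate-limiting enzyme of dopamine synthesis (chromosome 7, 142892752 to 142931128), was open in neither library, nor were Aldh1a1, Foxa2 and Lmx1b, although Foxa2 had a promoter peak of 2.16 in the replicated list. The list stood at 72.2% and 61.1% open, at percentiles of 13.4 and 1.46. Of 16 GABAergic genes 9 were open in both, with Zfpm2 (7.55), Zfpm1 (6.71), Gad2 (5.40), a GABA-synthesising enzyme, and Lhx1 (5.14). Helt and Lhx5 (2.78) were open in neither, Gata3 (4.11) was open in both, and Gata2 in a single library. Of 12 glutamatergic and tectal genes 8 were open in both, including Sim1 (7.55), Pou4f1 (7.39), Nkx6-1 (6.05) and Meis2 (4.10). Tfap2d (2.19) was open in neither library, and Pax7 and Tfap2b in a single library each. The GABAergic list was at percentiles of 0.290 and 4.04 and the glutamatergic and tectal list at 36.3 and 0.660, so that none of the 3 lists was below random in both libraries, which did not hold under other settings. In the IDR-thresholded lists all 3 were below random, with 19.4% of dopaminergic, 34.4% of GABAergic and 33.3% of glutamatergic and tectal genes open, and with −log10 q of at least 5 the dopaminergic (50%) and GABAergic (59.4%) lists were below it too, as was the GABAergic list with a window of 500 bp (68.8%).

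Hox genes, forebrain and hindbrain factors and isthmic organizer genes were open less often than genes of CpG-matched random lists. Of 27 Hox genes of groups 5 to 13, which pattern the trunk and spinal cord, only Hoxa7 (4.44) was open in both libraries and 23 were open in neither, among them Hoxa5, Hoxa6, Hoxa10 (2.34) and Hoxa11. The mean was 9.26% ± 2.62 open (SD, n = 2), against 91.0% in matched random lists. Forebrain factors were open in both libraries for 7 of 20 genes, with Arx (7.01), Lhx2 (6.19), Satb2 (4.11) and Neurod6 (4.00). Dlx2 (2.51), Emx1, Eomes (2.17) and Fezf1 were open in neither, as was Foxg1, a telencephalic factor with a peak of 2.75 in the replicated list. Hindbrain and cerebellar factors were open for 7 of 15, with Zic1 (6.80), Mafb (6.26), Egr2 (5.64) and Atoh1 (3.66). Gbx2 (2.91), Hoxa2, Hoxb1 and Hoxb2 were open in neither. The isthmic organizer list, named for the signalling centre between midbrain and hindbrain, had 8 of 16 open, with Dusp6 (12.9), Pax5 (9.13), Spry2 (8.94) and Spry1 (7.42), and the signals Fgf8 and Fgf17 open in neither. Its members En1, En2, Otx2 and Lmx1b are also in the dopaminergic list. Each of these 4 lists lay below random in both libraries. For forebrain factors this rested on the single libraries: in the replicated list made from both, 85% were open, within the random range. Against random lists not matched on CpG ratio, the forebrain (52.5%), hindbrain (50%) and isthmic (56.2%) shares were within the range, and of the 4 lists the Hox list alone stayed below it.

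Few cholinergic, motor and serotonergic neuron genes were open in both libraries. Of 10 cholinergic and motor neuron genes, the choline transporter Slc5a7 (3.69) and Isl1 (3.62) were open in both libraries, and Chat, Mnx1 (2.36), Phox2a (2.63) and Phox2b in neither. In the replicated list Chat shared a peak of 2.38 with another gene's start site. The list was below random in both libraries, with 50% and 20% open, but reached 80% in the replicated list, within the random range, and was also within it with a window of 2500 bp and against unmatched lists. Of 10 serotonergic genes, Tph2 (5.03), the serotonin-synthesising enzyme, Gata3 and Htr1a (3.09) were open in both, and Lmx1b, Maob and the serotonin transporter Slc6a4 in neither. The serotonergic list was at percentiles of 1.30 and 2.54, and was below random in the IDR-thresholded lists (10%) and in the replicated list (40%).

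Microglial, erythroid, liver, heart, gut and epidermal promoters were mostly open in neither library, while the vascular, meningeal, muscle and ependymal lists were mixed. The endothelial list was 50% open in replicate 1 and 31.2% in replicate 2, and the mural list 50% and 33.3%. Microglial genes were open in both libraries for 2 of 16, Hexb (6.19) and Irf8 (5.34), and closed for Aif1, C1qa, C1qb and C1qc (2.00). Endothelial genes were open for 5 of 16, with Abcb1a (4.51), Kdr (4.46), Esam (4.17) and Cldn5 (4.16), and closed for Cdh5, Emcn, Foxq1 and Ly6c1. Pericyte and mural genes were open for 3 of 12 (Kcnj8 4.25, Notch3 3.51 and Myh11 2.56), with Acta2, Anpep, Cspg4 and Foxs1 closed, and meningeal and fibroblast genes for 4 of 12, led by Pdgfra, Col1a1 (4.77), Foxc1 (3.74) and Tbx18 (3.47), with Col3a1, Dcn, Foxc2 and Lum closed. The ependyma and choroid plexus list had 8 of 14 open, with the ciliary genes Rsph1 (8.62), Foxj1 (8.01) and Dynlrb2 (6.68), while Ccdc153, Folr1, Kcnj13 and Tmem212 were closed. The peak of Enkur (14.03) also lay near the start site of another gene. Erythroid genes were open for 2 of 13 (Tal1 4.80 and Gypa 3.90), with Alas2, Epb42, Gata1 and the globin gene Hba-a1 closed. Liver genes were open for 1 of 16 (Afp 3.12), with Ahsg, Alb, Apoa2 and Cps1 closed, and heart genes for 1 of 12 (Nppa 3.13), with Gata4, Myh6, Myl2 and Myl7 closed. Gut epithelial genes were open for 0 of 12, with Cdh17, Cdx1, Cdx2 and Fabp1 among the closed, and skeletal muscle genes for 4 of 16, with Acta1, Myf5, Myf6 and Myh3 closed. In the muscle list, the peaks of Actn3 (13.1) and Mylpf (10.6) lay near start sites of other genes, and Ryr1 (7.53) and Pax3 (2.77) had their own. Of 14 epidermal genes Perp (5.32) and Krt1 (4.86) were open, and Dsc3 (3.04), Dsg1a, Flg and Grhl3 were closed. The epidermal and gut lists lay below random in both libraries, but with a window of 2500 bp both (35.7% and 8.33%) were within the range, as was the epidermal list in the replicated list (28.6%). The microglial, vascular, meningeal, ependymal, erythroid, liver, muscle and heart lists were not outside the random range in both libraries, but in the IDR-thresholded lists the endothelial (6.25%), meningeal (4.17%) and heart (0%) lists were below it.

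**Figure D2:**
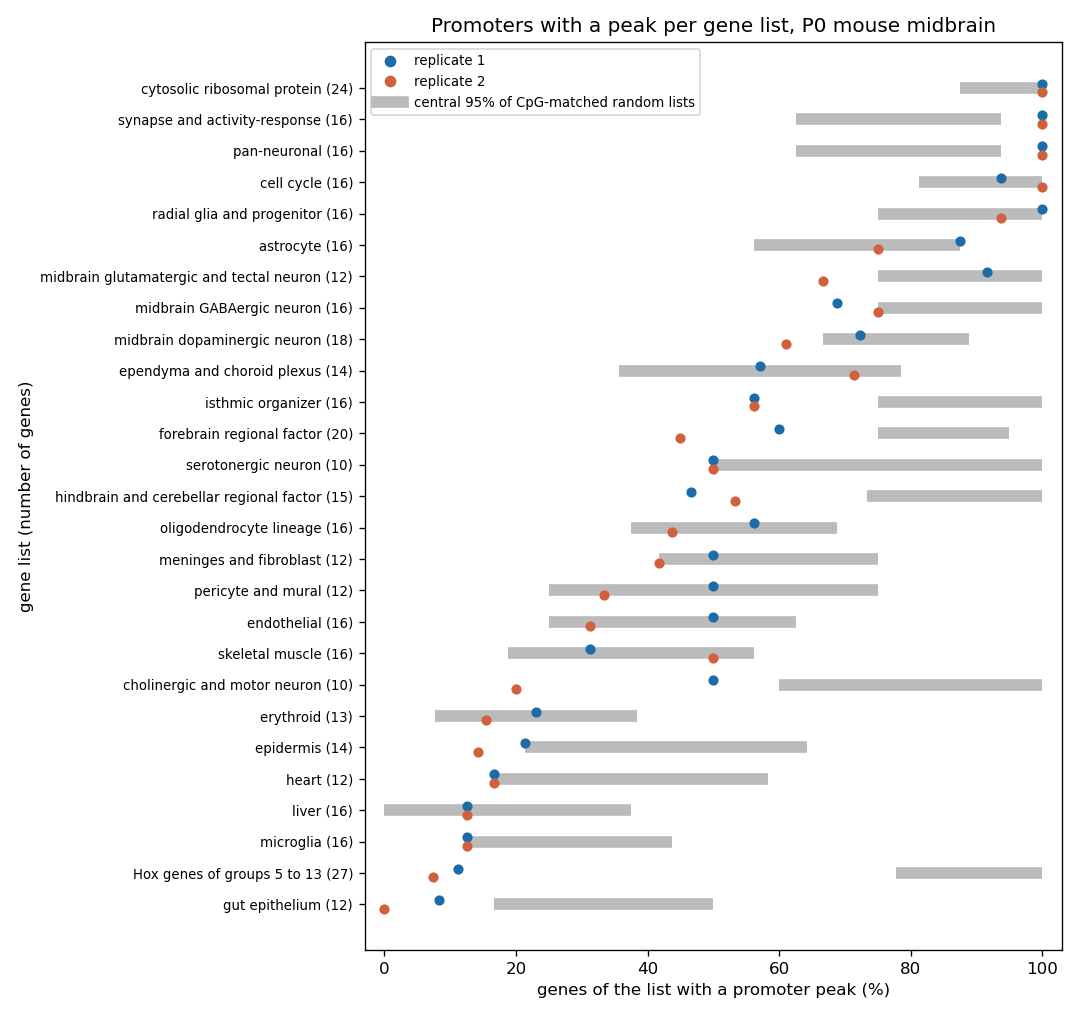
Share of genes in each of the 27 lists with a promoter peak (%), per replicate (points), with the central 95% of random lists matched on promoter CpG ratio (grey bars, the wider limits of both libraries); numbers of genes are in parentheses. Pan-neuronal and synapse genes sit at 100% in both replicates, and Hox genes of groups 5 to 13 at 11.1% and 7.41%.

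Distal peaks were more frequent than in random lists around pan-neuronal, astrocyte, oligodendrocyte lineage and radial glia genes. Pan-neuronal genes had 7 ± 1.06 distal entries per gene (SD, n = 2), 2.5 times the mean of random lists matched on territory, led by Myt1l, a neuronal transcription factor (25 and 18 entries in replicates 1 and 2), Celf4 (21 and 20) and Map2 (13 and 8). Astrocyte genes had 6.38 ± 0.265 (SD, n = 2), or 2.92 times random, with Nfib (22 and 25), the glutamate transporter Slc1a3 (14 and 18) and Aldh1l1 (14 and 14). Oligodendrocyte lineage genes had 3.5 ± 0.530 (SD, n = 2), or 2.69 times random, led by Mbp, a major myelin protein (11 and 9), Cldn11 (9 and 5) and Opalin (8 and 5), whose own promoter was closed. Radial glia and progenitor genes had 5.09 ± 0.0442 (SD, n = 2), or 2.32 times random, with Notch1 at 16 and 14 and Hes1 at 11 and 6. Slc1a3, which has the most in this list, and Sox9 (9 and 8) are members of the astrocyte list too. The excesses of the astrocyte and radial glia lists are therefore not independent. These 4 lists were the only ones above random in both libraries, and no list was below in both. In replicate 1 alone the GABAergic, glutamatergic and tectal and isthmic lists were also above and the Hox list below, and in replicate 2 alone the synapse list was also above. Against unmatched lists the Hox list was below in both libraries. In the IDR-thresholded lists the radial glia (0.938) and oligodendrocyte (1.06) lists were within the random range, as was the radial glia list with each region counted once (3.09).

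Lmx1b, Foxa2 and Lhx5, whose promoters were closed in both libraries, had distal peaks nearby. Lmx1b (chromosome 2, 33560965 to 33640511) had 13 entries in replicate 1 and 6 in replicate 2, Foxa2 had 7 and 5, and Lhx5 had 8 and 3. Among midbrain genes open in both libraries, En2 had 8 and 7, the proneural factor Ascl1 13 and 8, Meis2 22 and 9 and Pax3 8 and 3. Of those open in a single library, Nkx2-2 had 5 and 5 and Pou4f2 7 and 4. Th had 2 and 1, and Slc6a3 had 0 in both. The dopaminergic list averaged 2.86 ± 0.668 (SD, n = 2), the GABAergic list 3.25 ± 0.884 (SD, n = 2) and the glutamatergic and tectal list 4.08 ± 1.89 (SD, n = 2), where replicate 1 had 5.42 and replicate 2 had 2.75. Hox genes of groups 5 to 13 had 0 entries in replicate 1 and 1 in replicate 2, at Hoxd12. In the microglial list, Ptprc had 4 and 5 entries and Spi1, the gene of the myeloid factor PU.1, 6 and 3. The highest counts were 8 and 6 at Cdh5 among endothelial genes, 6 and 6 at Notch3 among mural genes, 7 and 5 at Foxc1 among meningeal genes and 6 and 3 at Kl among ependymal and choroid plexus genes. Among regional factors, Tbr1 had 8 and 6, Olig3 7 and 4, Gbx2 7 and 3, and Sp8 8 and 5, and among activity-response genes Fos had 6 and 7, Fosb 6 and 3 and Nr4a1 5 and 4. Over all genes, the largest numbers were at Bach2 (36 and 28), Frmd4a (35 and 29), Maml3 (32 and 24), Nav2 (32 and 23), Dclk1 (35 and 19), Pde4d (32 and 20), Gse1 (29 and 22), Nfib, Tns1 (28 and 19) and Usp29 (30 and 17), whose promoter peak also lay near another gene's start site.

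**Figure D3:**
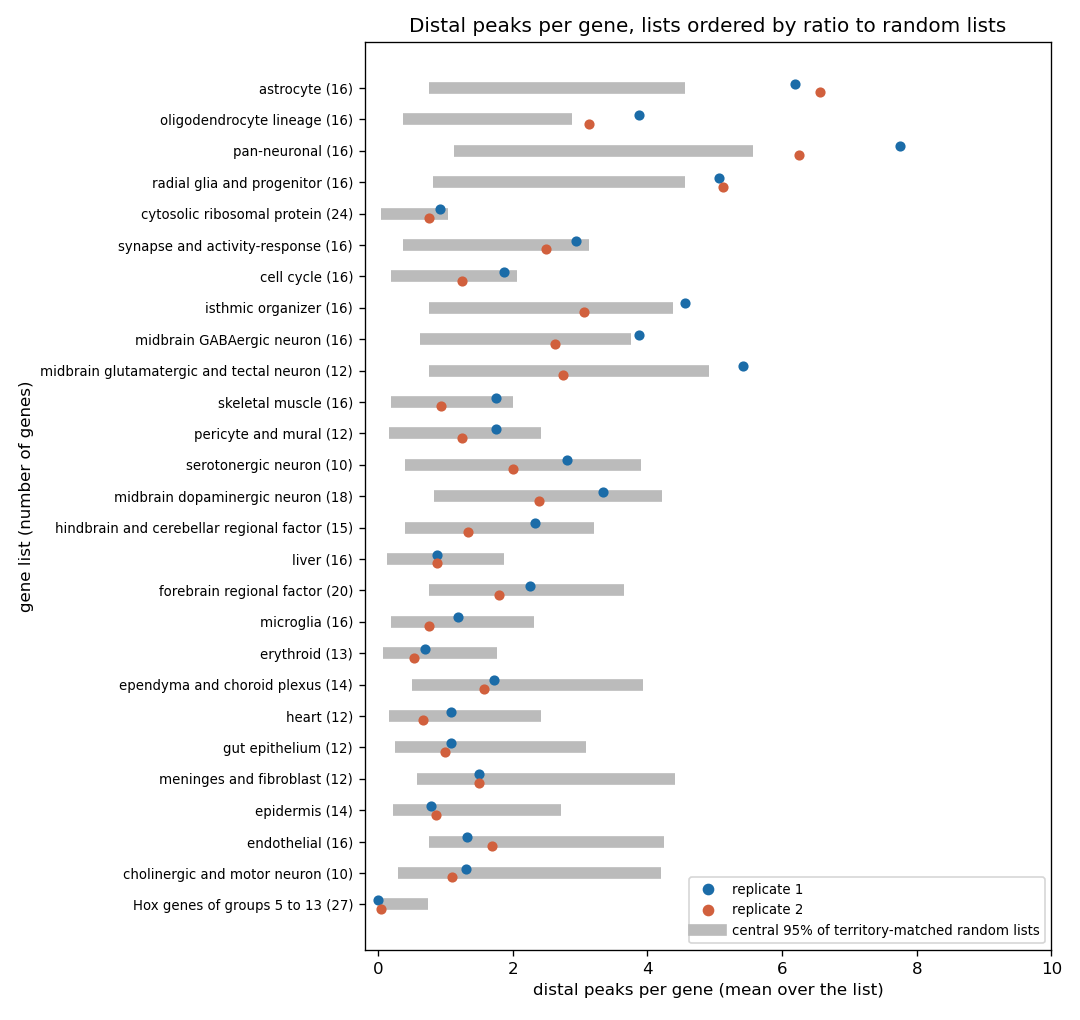
Mean number of distal peak entries per gene in each list, per replicate (points), with the central 95% of random lists matched on territory (grey bars, the wider limits of both libraries), ordered by the ratio to random. Astrocyte, oligodendrocyte, pan-neuronal and radial glia genes lie above the bar in both replicates.

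**Figure D4:**
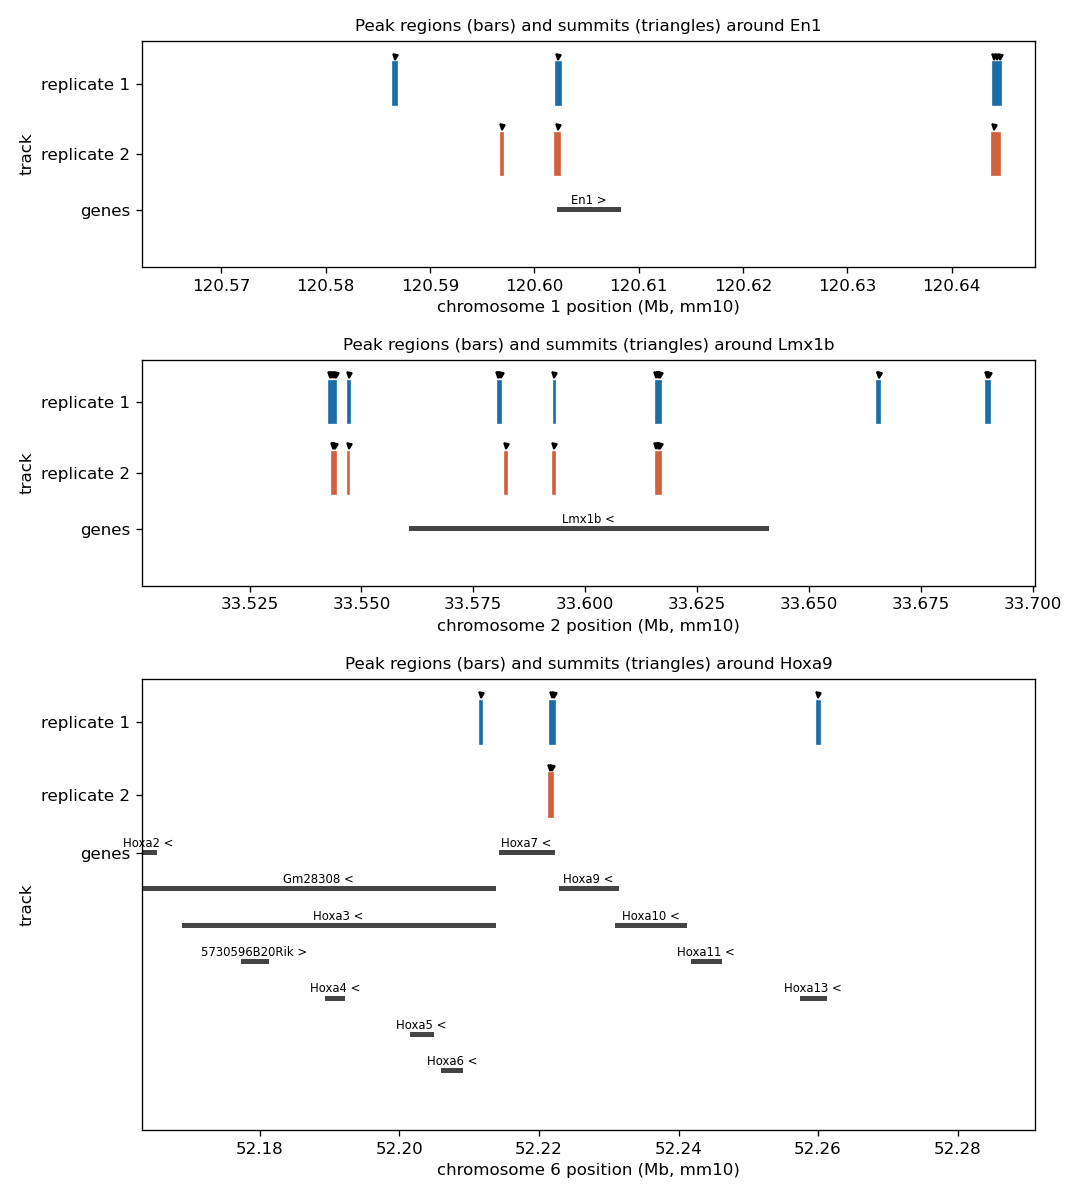
Peak regions (bars) and summits (triangles) of each replicate and protein-coding genes (dark lines, arrowhead for strand) around En1, Lmx1b and the HoxA cluster, with position in Mb on mm10. En1 has a peak at its start site in both replicates, the peaks around Lmx1b lie away from its start sites, and in the HoxA cluster both replicates share the region at Hoxa7.

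Motifs set distal and promoter peaks apart. At distal summits the RFX motif, bound by factors of ciliary and neuronal genes, was 69.2 ± 41.2 times as frequent as in flanks (SD, n = 2), a wide spread because only 16 and 6 flank windows held it. CTCF, the insulator protein's motif, was in 4.62% ± 0.351 of distal windows, a ratio of 37.7 ± 0.327 (SD, n = 2). NRF1 followed at 6.53 ± 1.29, NFI at 5.36 ± 2.94, CRE at 4.10 ± 1.07 and SP and KLF at 3.97 ± 0.324 (SD, n = 2 each). The NFI value rested on 18 and 28 distal windows. The lowest ratios were those of FOX (0.549 ± 0.0601), HNF1 (0.569 ± 0.366) and NR4A (0.571 ± 0.0618; SD, n = 2 each). The HNF1 value rested on 5 and 1 distal windows, with ratios of 0.828 and 0.310. The FOX ratio depended on the background, and was 1.37 against shuffled motif positions. Other motifs, chosen after their values were seen, were described at promoters: there NRF1 reached 71.2, YY1 20.2, RFX 17.1, CRE 14.1, ETS 12.9, SP and KLF 12.8 and CTCF 7.54. The flanks were not matched to the summits on base composition. Against shuffled motif positions 22 promoter ratios moved by at least their SD, a further 6 crossed 1 and 1 stayed the same. The size of a promoter ratio thus depends on the background. Of the 30 motifs, only NFI exceeded 1.5 at distal peaks while staying below 1.1 at promoters (1.02). That promoter ratio rested on 5 and 6 windows, with 0.920 in replicate 1 and 1.13 in replicate 2, and was 1.93 with a window of 50 bp, so the contrast is not firm. The E-box CAGCTG, the site of ASCL1, had ratios of 2.03 and 1.36, and the E-box CAGATG, the site of NEUROD and NEUROG factors, 1.21 and 0.611. The promoter ratio of CAGATG was 1.89 against shuffled motif positions.

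**Figure D5:**
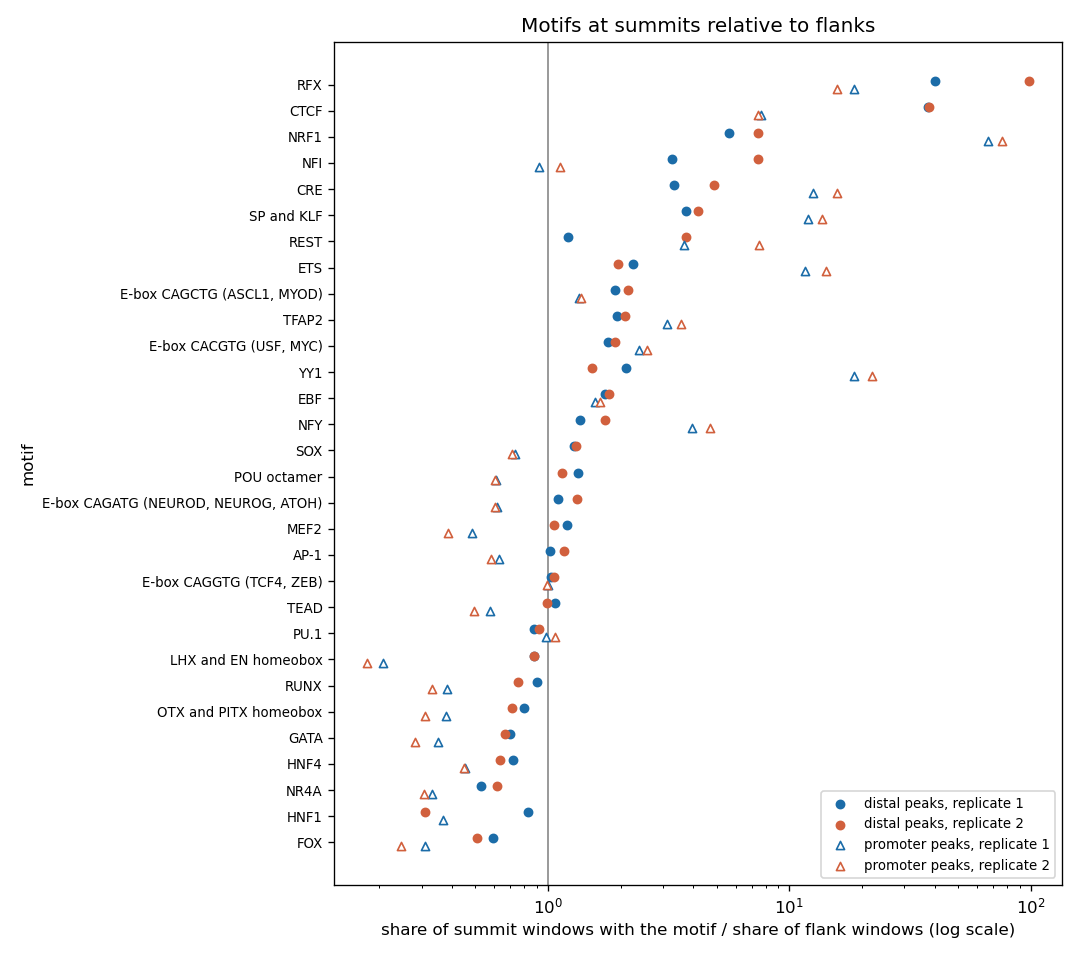
Share of summit windows with each motif over the share in flank windows (log scale), at distal (filled circles) and promoter peaks (open triangles), per replicate; a ratio of 0, for HNF1 at promoters in replicate 2, is not drawn. RFX and CTCF lead at distal peaks, and NRF1 leads at promoters, at 66.2 and 76.2.

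The strongest entries outside promoters in the replicated list lay mostly in intergenic sequence. The first lay on chromosome X (143482936 to 143483180, signal value 55.1, 35531 bp from Pak3), then came 2 on chromosome 2 (69355469 to 69355735, 54.2, and 3964421 to 3964690, 45.7, in intergenic sequence near Abcb11 and Frmd4a). Next were an intronic entry on chromosome 10 (96077546 to 96077953, 40.6), an intergenic one on chromosome 5 (60042756 to 60043150, 38.7) and one at a non-coding start site on chromosome 4 (80002696 to 80003057, 29.0). A region on chromosome 12 (97061368 to 97061856) held 2 of the entries, at 28.2 and 26.01. The last were on chromosome 16 (17222195 to 17222580, 26.5) and chromosome 8 (19784430 to 19785047, 25.9). Of these 10 entries, 5 matched the mitochondrial genome at 80% identity or more over at least 50% of their length. The entry on chromosome 2 at 69355469 to 69355735 fell just short, matching over 48.3% of its length with a best identity of 100%.

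Peak density differed between chromosomes. Chromosome 11, which has 13.8 protein-coding genes per Mb, had 38.3 ± 6.98 entries per Mb (SD, n = 2), and chromosome X, with 5.80 genes per Mb, had 12.97 ± 2.32 (SD, n = 2). Chromosomes 12 and 18, with 5.50 and 5.83 genes per Mb, had 26.5 ± 4.84 and 28.3 ± 4.62 (SD, n = 2 each). Chromosome X was thus also low beside autosomes of similar gene density. The density of chromosome X was 0.431 ± 0.0122 of the autosomal density (SD, n = 2). Chromosome Y had 16 and 23 entries, or 0.221 ± 0.0562 per Mb (SD, n = 2).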

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

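Chosen after the results were seen were the use of the planned comparison with CpG-matched lists as a test on the Hox genes, the second measure of masking, the search of unplaced contigs, the motif test of cell mixture, and the rule that an interval must lie inside its predicted range. The ranked lists, which the comparisons did not use, held 160 entries of replicate 1 and 180 of replicate 2 on unplaced contigs, above the limit of 3 that a count of 0 allows. They also held 1414 entries of replicate 1 and 1806 of replicate 2 on chromosomes that are missing from the pseudoreplicated lists. Of the 1217 and 1630 regions that these formed away from the pseudoreplicated peaks, only 1 in each library matched the mitochondrial genome, over 100% of its length (chromosome 1, 24611586 to 24616160 in replicate 1, signal value 3.19), while the 5 strongest in each library matched it over 0%. The strongest, on chromosome 9 (24541943 to 24542230 in replicate 1), had signal values of 44.6 and 46.4 in replicates 1 and 2. One on chromosome 6 (103648979 to 103649356 in replicate 1) had 42.4 and 42.8. Strong signals were thus among the missing entries, and the sources used here do not say why they are missing.

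The strongest 10 entries outside promoters were tested for copied sequence. Another copy on the chromosomes was found for 2 of the 10 and a match to an unplaced contig for 1, which argues against either as the general source. Of the 10, 5 entries in 4 regions matched the mitochondrial genome, between the 8 that would have pointed to nuclear copies of mitochondrial DNA and the 2 that would have argued against them, so this source cannot be told apart from others for the set. The entries on chromosome X (143482936 to 143483180), chromosome 2 (3964421 to 3964690) and chromosome 16 (17222195 to 17222580) matched none of these sequences. No biological explanation was tested.

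The closed promoters of Hox genes of groups 5 to 13 were weighed against depth, CpG content and repeats. Of the 23 members closed in both libraries, 2 (Hoxa10 and Hoxd9) had a promoter peak in the list of both libraries pooled, within the bound of 3 set against depth. That list also held a peak for only 1 of 7 closed hindbrain and 1 of 6 closed isthmic genes, but for 3 of 6 forebrain factors. Pooling adds only the depth of the other library, and low counts arose elsewhere too, so the count does not decide on depth. The open share of 9.26% lay below the lower limit of 77.8% for CpG-matched lists. The median soft-masked share of these promoters was 9.60% (95% interval 7.85 to 10.9%), against 8.25% for open promoters in the same CpG bins. It was higher, as predicted if masking were the cause, but the interval holds 8.25%. Of 6711 other genes masked as much or more, 78.6% were open, which argues against masking as the whole cause. That share was below the 91.0% of CpG-matched random lists, so a smaller part of masking is left open. No biological explanation was tested, since the design holds a single tissue.

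Distal summits fell in general, from 36369 in replicate 1 to 28928 in replicate 2. At 93 neuronal genes the fall was near the general one, from 377 to 276, a ratio of 0.732. At 45 genes of the astrocyte, oligodendrocyte and radial glia and progenitor lists, called glial here, it was smaller, from 214 to 206, a ratio of 0.963. The ratio of ratios was 1.31 (95% bootstrap interval over genes 1.05 to 1.63). This interval resamples the genes in which the difference was seen. It holds no spread between pools, so it does not show that the difference would recur in other pools. The lists were not alike: from replicate 1 to replicate 2 the mean per gene was 6.19 and 6.56 for astrocyte and 5.06 and 5.13 for radial glia genes, but 3.88 and 3.13 for oligodendrocyte genes and 7.75 and 6.25 for pan-neuronal genes. Among the neuronal lists the fall was steepest for glutamatergic and tectal genes (5.42 and 2.75). It was smaller for synapse (2.94 and 2.5) and cholinergic and motor neuron genes (1.3 and 1.1). Counting each region once left it at 1.28 (1.05 to 1.55), which argues against several summits per region as the whole cause. In distal peaks of a single library, the NFI motif was 3.73 times as frequent in those of replicate 2, on 14 and 5 windows. The E-box CAGATG was also more frequent there (24.4% against 16.8%), opposite to what more neurons in replicate 1 predicted. A short consensus does not show which factor or cell type uses a site, so this does not decide on another mix of cells. No other biological explanation was tested. With the same number of strongest distal entries in each library the neuronal counts were nearly equal (282 in replicate 1, 276 in replicate 2) and the glial counts higher in replicate 2 (170, 206), so the deficit at neuronal genes was nearly gone, but the ratio was 1.24 (0.998 to 1.54), just inside the range predicted if the longer list of replicate 1 were the cause, with an interval that also holds 1.31, so for the ratio the list length cannot be told apart from other causes.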

How the results depend on the processing

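The count of genes with an open promoter stayed within 1.5 times under all 8 alternatives. No replicate could be left out of the consistency ratios, which were not run again. Alternatives with the basic transcript set, regions counted once and soft-masked summits left out were chosen after seeing the data; the cause was not tested for any change below unless stated. Depth, which the peak lists do not hold, limits how a missing weak peak can be read.

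Entries numbered 44232 and 33749 in the IDR-thresholded lists and 39730 and 38078 as merged regions, and 40758 in replicate 2 with −log10 q of at least 5. Overlap of entries was 65.6% and 71.2% with a reciprocal overlap of 50%, 83.3% and 92.5% in the IDR-thresholded lists, and 79.7% and 90.6% with the stricter q. Overlap of equal numbers of the strongest regions was 68.5% and 71.2%. The promoter share was 44.2% with a window of 500 bp, 55.5% with 2500 bp (by construction) and 76.9% in the IDR-thresholded lists. The density of chromosome X relative to autosomes was 0.547 in those lists.

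Promoter lists left their side of random in these cases: with 2500 bp, cholinergic and motor (50%), epidermal (35.7%) and gut genes (8.33%); in the replicated list, cholinergic and motor (80%), forebrain (85%) and epidermal genes (28.6%); in the IDR-thresholded lists, synapse genes (84.4%); and against unmatched random lists, cholinergic and motor (35%), forebrain (52.5%), hindbrain (50%) and isthmic genes (56.2%), whose open shares do not move there. Other lists crossed to a call: promoter lists below random numbered 14 in the IDR-thresholded lists, 10 with 500 bp, 9 with the stricter q and 9 with the basic transcript set, against 7. The lists added were dopaminergic (19.4%), GABAergic (34.4%), glutamatergic and tectal (33.3%), serotonergic (10%), endothelial (6.25%), meningeal (4.17%) and heart genes (0%) in the IDR-thresholded lists, GABAergic (68.8%), serotonergic (40%) and meningeal genes (37.5%) with 500 bp, dopaminergic (50%) and GABAergic genes (59.4%) with the stricter q, and GABAergic (65.6%) and serotonergic genes (40%) with the basic set. In the replicated list serotonergic genes (40%) were added, and 9 and 10 lists were below random without replicate 1 and without replicate 2. Against unmatched lists microglial, erythroid, liver and heart genes came below random, and radial glia, cell cycle and ribosomal genes above it. Hox and pan-neuronal promoters kept their side throughout. Without a replicate every called list kept its side by construction, since a call already required that side in each library alone. The Hox list was then at 7.41 to 11.1%. For distal peaks, the radial glia list fell within random in the IDR-thresholded lists (0.938 per gene) and with regions counted once (3.09), and the oligodendrocyte list in the IDR-thresholded lists (1.06). Distal lists above random numbered 7 with a limit of 50000 bp, where GABAergic (2.78), isthmic (3.41) and synapse genes (2.53) were added, 5 with 200000 bp, 5 with regions counted once, 3 in the IDR-thresholded lists, 8 against unmatched lists, 5 without replicate 1 and 7 without replicate 2, against 4. The Hox list came below random without replicate 2 (0 per gene) and against unmatched lists (0.0185), the only list below in any setting.

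The distal CTCF ratio was 48.9 with a window of 50 bp, 224 against shuffled motif positions, 23.2 in the IDR-thresholded lists and 38.4 without soft-masked summits. The RFX ratio was 138 with 50 bp and 176 against shuffled positions, and 40.1 to 98.3 without a replicate; the NFI ratio was 1.91 against shuffled positions and 3.28 to 7.44 without a replicate. Against shuffled positions the ratio crossed 1 for distal LHX and EN (1.01), RUNX (1.17), FOX (1.37), PU.1 (1.08) and HNF4 (1.499), and for promoter CAGATG (1.89), POU octamer (4.04), TEAD (1.30), FOX (1.61), HNF4 (1.91) and EBF (0.754). In the IDR-thresholded lists it crossed 1 for distal CAGGTG (0.873) and MEF2 (0.799).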

Other observations

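The distal peaks found in a single library differed in their motifs, a comparison chosen after the data were seen. CTCF sites were in 4.87% (95% interval 4.53 to 5.23%) of the summit windows of distal peaks found in replicate 1 alone and in 2.18% (1.92 to 2.47%) of those found in replicate 2 alone, and the SP and KLF motif in 4.62% and 3.25%. The E-box CAGCTG went the other way, with 17.0% and 19.7%, as did NFY, with 2.12% and 2.66%. SOX sites were in 4.26% and 4.18%, with overlapping intervals. These values compare 2 libraries and have no replicate check.

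Promoters closed in both libraries were looked up in the list of both libraries pooled. A peak was found there for 3 of 6 closed forebrain factors, 2 of 5 cholinergic and motor neuron genes, 1 of 2 GABAergic, 1 of 1 glutamatergic and tectal and 1 of 2 astrocyte genes. It was found for 1 of 6 isthmic, 1 of 7 hindbrain, 1 of 7 oligodendrocyte, 1 of 10 erythroid, 1 of 11 epidermal and 1 of 14 microglial genes. It was found for 0 of 4 dopaminergic, 0 of 3 serotonergic, 0 of 8 endothelial, 0 of 5 mural, 0 of 5 meningeal, 0 of 4 ependymal, 0 of 7 muscle, 0 of 9 heart, 0 of 13 liver and 0 of 11 gut genes. The replicated list, also made from both libraries, was not used for this and differed. It held a peak (2.16) at the closed dopaminergic gene Foxa2. In it 8 cholinergic and motor neuron genes were open, against 7 in the pooled list, but 4 serotonergic genes against 7.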
